A study of Mus musculus with 8 samples.

How the data were processed

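RNA from 8 samples of NMuMG cells, extracted with RNeasy per the labels' protocols, was labelled with biotin and hybridized to 8 one-colour Affymetrix arrays that measure whole transcripts. The deposited values are log2 signal intensities for 34760 probe sets. Their log base is inferred from their range, 1.85 to 13.80, and is not stated. Per the submitters' processing notes the values were made with oligo 1.14.0. How background was corrected, how probes were summarized and whether probe sets were filtered is not given in the sources used here. No normalization was applied here for the reported values.

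Genes were probe sets with exactly 1 gene symbol: 21640 had 1, 1321 had several and 11799 had none. Of these, 21553 matched a reference gene by its ID, and 87 did not. Probe sets with several symbols or none were left out, and genes measured only by them were not analysed here. For 954 genes with more than 1 probe set, the probe set with the highest mean was taken, which left 19937 genes. No filter on brightness was applied. The reference gene table (GRCm38.p6) served for names only. Genes with near-identical copies may share probes, which was not tested.

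Groups were siControl, siSox4, siControl with TGFβ and siSox4 with TGFβ, each with 2 arrays. In R 4.3.3, limma 3.58.1 was fitted to all 8 arrays with 1 coefficient per group (lmFit and eBayes, 4 residual degrees of freedom, 4.77 prior degrees of freedom). The contrasts were siSox4 against siControl without TGFβ, the same with TGFβ, TGFβ against none in siControl cells, the same in siSox4 cells, and the difference between these TGFβ effects. P-values were adjusted by the Benjamini-Hochberg method over all genes, and genes with an adjusted p under 0.05 were called. Log2 fold changes are siSox4 minus siControl, or TGFβ minus none. Fold changes on arrays can be smaller than those in RNA, and siRNA off-target effects were not tested.

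Lists of genes were fixed before the files were opened, 25 in all: mesenchymal and EMT, epithelial adhesion and junction, TGFβ and SMAD target, actin cytoskeleton and focal adhesion, extracellular matrix and remodelling, S phase and DNA replication, mitosis, Polycomb and chromatin repressor, Sox family (without Sox4), Wnt pathway, Notch, Hedgehog and EGFR ligand pathway, interferon response, inflammatory and NF-kB, p53 target and apoptosis, unfolded protein and amino acid stress, sterol and fatty acid synthesis, oxidative phosphorylation, ribosomal protein, and keratins and cornified epithelium genes, with markers of luminal, basal and myoepithelial, fibroblast, endothelial, leukocyte and neuronal cells. Each was tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, adjusted over the 25 lists within a comparison. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move on balance, without comparing them with other genes. Camera with an estimated correlation tests on the 4 residual degrees of freedom, and the preset form on far more. A call lost with the estimate can therefore not be credited to correlation between genes alone. Where the estimate lay below 0.01, such a loss is not due to a higher correlation between genes. Counts are also given with p-values adjusted over a list alone.

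Named genes were chosen by a rule fixed in advance. For each comparison it takes Sox4 and the 6 largest rises and 6 largest falls among called genes whose groups do not overlap (for the difference of the TGFβ effects, among called genes), passing over clone names, gene models and pseudogenes. It adds up to 4 members with the smallest adjusted p from each list that passed camera or had at least 3 called members. Whatever their values, Cdh1, Cdh2, Vim, Fn1, Ncam1, Zeb1, Zeb2, Snai1, Ezh2, Eed, Suz12, Smad7 and Id1 were looked at too. The text gives a part of the members so chosen.

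The TGFβ responses of siControl and siSox4 cells were compared by the median ratio of their effects over genes whose mean TGFβ effect was called, with fry as the test. Shared calls were set against the number for independent lists. Fisher's exact test was one-sided. The correlation that shared control arrays bring was simulated in 100 draws.

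The scripts were tested on simulated data. A log2 change of 0.5 was recovered in 61.2%, 62.7%, 62.7%, 68.7% and 22.4% of the changed genes in the 5 contrasts in the order given, and a change of 1 in 100%, 97.0%, 100%, 100% and 95.5%. False calls made up 2.25%, 3.89%, 10.3%, 8.67% and 8.23% of all calls. These shares rest on 4, 7, 20, 17 and 13 false calls in a single draw per contrast. Each size of change was put into only 66 or 67 of 19937 genes. In the data 12.4% to 21.7% of the genes were called in the 4 comparisons of groups, so recovery there may differ. A simulated ratio of 0.7 between the TGFβ responses came back as 0.705, and a ratio of 1 as 0.999. A shift of 0.3 put into the actin list was called (camera, adjusted p = 5.34e-32), with 0 other lists called. The simulated genes varied independently of each other. This test therefore cannot show how often camera falsely calls lists of correlated genes.

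Alternatives were quantile normalization again, centring each array on its median, leaving out the dimmest 25% or 50% of the genes, the mean of all probe sets of a gene, testing every probe set on its own, eBayes with trend or robust settings, array weights, a replicate block, leaving out each array, and fitting only the 4 arrays compared. Leaving out replicate 2 of both siControl groups, and a crossed block, were added after the data were seen. With 2 arrays in a group, neither a test for outlying arrays nor one of other splits of the arrays was made.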

Results

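Expression was measured in NMuMG cells, an epithelial line from mouse mammary gland in which the growth factor TGFβ is widely used to drive an epithelial-to-mesenchymal transition (EMT). The cells received either control siRNA (siControl) or siRNA directed at Sox4 (siSox4), which codes for a transcription factor of the SRY-related HMG-box family, and were kept either untreated or with 2 ng/ml TGFβ for 2 days. Each of the 4 groups held 2 arrays, 8 in all. The deposited values were used as they are, and the median value of an array lay between 4.80 and 4.98 on the log2 scale. The first principal component, with 54.0% of the variance, separated arrays with and without TGFβ, and the next one, with 27.4%, separated siSox4 from siControl. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.10, and that of a difference between a pair of fold changes was 0.14. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

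Sox4 itself was reported first because it is the siRNA target. Its signal was 9.48 and 9.38 in the siControl arrays and 7.58 and 7.59 in the siSox4 arrays without TGFβ. With TGFβ it was 10.56 and 10.59 in siControl and 8.99 and 8.83 in siSox4. Sox4 fell by 1.85 (SE 0.09) on the log2 scale with siSox4 in untreated cells, to 27.7% of the siControl level (limma, adjusted p = 2.28e-05). In TGFβ-treated cells it fell by 1.66 (SE 0.09), to 31.6% (adjusted p = 8.12e-06). TGFβ raised Sox4 from a mean of 9.43 to 10.57 in siControl cells (adjusted p = 2.86e-05) and by 1.33 in siSox4 cells (adjusted p = 1.28e-05), and the difference between these effects, 0.19 (SE 0.12), did not pass (adjusted p = 0.467). The Sox4 level left in siSox4 cells with TGFβ, 8.91 on average (SD 0.11, n = 2), compared with 9.43 (SD 0.07, n = 2) in untreated siControl cells. The plot of signal per array shows Sox4 beside 5 other genes.

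**Figure D1:**
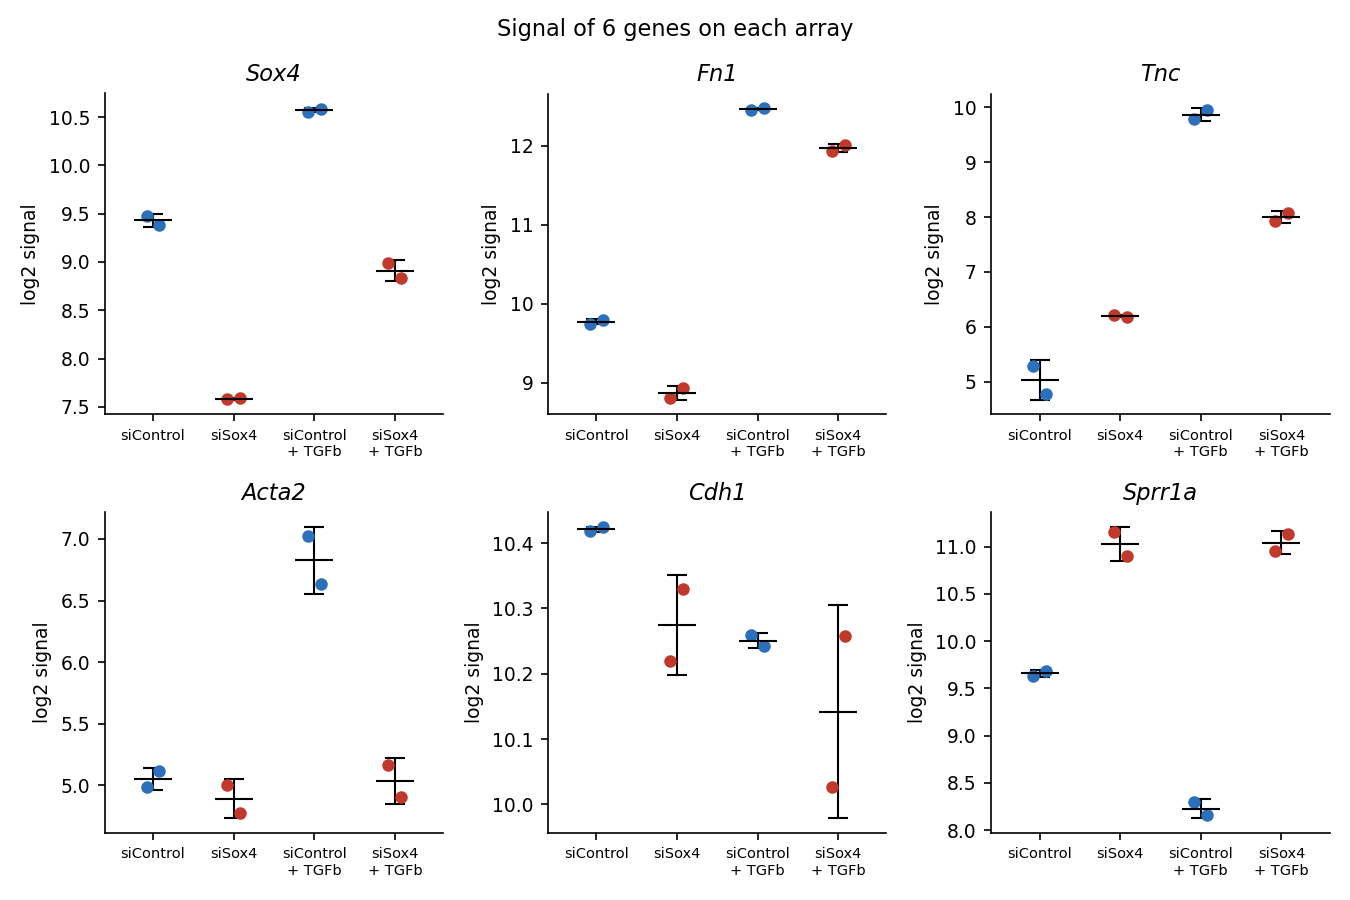
Log2 signal (y axis) of Sox4, Fn1, Tnc, Acta2, Cdh1 and Sprr1a in each of the 8 arrays (points), grouped on the x axis by treatment, with siControl in blue and siSox4 in red. Horizontal lines are group means and error bars the SD of n = 2 arrays; the mean of Sox4 fell from 9.43 to 7.58 without TGFβ and from 10.57 to 8.91 with TGFβ.

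The comparison of siSox4 with siControl cells in the absence of TGFβ asks which genes depend on Sox4 in untreated cells. Among the largest rises with siSox4 were Adam9, a membrane metalloprotease, at 2.26 on the log2 scale (SE 0.08, adjusted p = 1.85e-05), and Tmigd1, a membrane protein of epithelia, at 2.14 (SE 0.09, adjusted p = 2.28e-05). Cyp4a12b and Cyp4a12a, fatty acid hydroxylases so alike in sequence that their probe sets may not tell them apart, rose by 2.67 and 2.55. Tm4sf20 and Bpifc rose by 2.25 and 2.17. The largest falls, beside Sox4, were Klhl24 at -2.18, the matrix peroxidase Pxdn at -2.11, the TEAD-family transcription factor Tead2 at -1.74, Ly6e at -1.71 and cyclin D2 (Ccnd2) at -1.63. All 12 of these genes were also called when any single array was left out.

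Genes that copy DNA and drive cell division were lower in siSox4 cells. Of 34 measured S phase and DNA replication genes, 22 fell and 1 rose (adjusted over the list alone, 25 fell and 1 rose), with a median of -0.41. Orc1, a subunit of the origin recognition complex, fell by 0.86, Chaf1b, a chromatin assembly factor, by 0.75 and the helicase subunit Mcm7 by 0.66. The gene that rose was Ccne1 (0.66), which codes for cyclin E1. Of 34 mitosis genes, 14 fell and none rose (17 adjusted over the list alone), among them the kinetochore gene Ndc80 (-0.84), Bub1 (-0.61) and Aurkb (-0.53). Camera with a preset correlation called both lists, with adjusted p = 1.21e-13 for S phase and 3.27e-09 for mitosis. With an estimated correlation neither was called (adjusted p = 0.443 for each).

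Lipid synthesis genes and inflammatory genes moved in opposite directions. In the sterol and fatty acid synthesis list, 5 of 21 genes fell and 1 rose (adjusted over the list alone, 9 and 2), with Acly, the source of cytosolic acetyl-CoA, at -1.46 and the sterol sensor Insig1 at -0.98 (camera, adjusted p = 0.00155, against 0.512 with an estimated correlation). In the inflammatory and NF-kB list, 9 of 26 genes rose and 1 fell (the same counts adjusted over the list alone). The chemokines Ccl20 and Ccl2 rose by 1.57 and 1.52 and the NF-kB subunit Nfkb2 by 0.77. Camera gave adjusted p = 0.0103 for this list, which became adjusted p = 0.443 with an estimated correlation. Interferon response genes, which foreign RNA can switch on, moved little: 1 of 30 rose and none fell (0 adjusted over the list alone; adjusted p = 0.903).

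The EMT-related lists did not pass without TGFβ. Of 34 mesenchymal and EMT genes 5 rose and 4 fell (camera, adjusted p = 0.818; adjusted over the list alone, 6 and 5). Fibronectin (Fn1) fell by 0.90 (SE 0.08, adjusted p = 0.000358) and Ncam1 by 0.67 (adjusted p = 0.00341), whereas tenascin C (Tnc) rose by 1.16 and Sparc by 0.78. Of the 30 actin cytoskeleton and focal adhesion genes 4 rose and 3 fell (adjusted p = 0.861; same counts adjusted over the list alone), with integrin Itga2 at 1.71, Actn1 at 0.89 and Palld at -0.91. Of 37 epithelial adhesion and junction genes 3 rose and 3 fell (adjusted p = 0.903; 4 and 3 adjusted over the list alone). E-cadherin (Cdh1, -0.15), N-cadherin (Cdh2, 0.17), vimentin (Vim, 0.03), Snai1 (-0.07), Zeb2 (-0.35), Id1 (0.29) and Smad7 (-0.23) were not called. Zeb1 was called at 0.50 (adjusted p = 0.0145), but not without siControl replicate 2 (0.41, adjusted p = 0.0807) or siSox4 replicate 2 (0.38, adjusted p = 0.114).

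Of 29 TGFβ and SMAD target genes 6 rose and 2 fell (adjusted p = 0.065; 9 and 2 adjusted over the list alone), including thrombospondin 1 (Thbs1) at 1.42, Ccn2 at 0.61 and the cell cycle inhibitor Cdkn2b at 0.56. Extracellular matrix genes gave 6 rises and 3 falls of 35 (adjusted p = 0.06, same counts adjusted over the list alone), led by the collagenase Mmp13 at 1.98 and the laminin chain Lamb3 at 0.75. Of 21 keratins and cornified epithelium genes 3 rose (adjusted p = 0.119, 3 adjusted over the list alone), among them Sprr1a at 1.37 and Perp at 1.13. Of 29 Polycomb and chromatin repressor genes 7 fell and 2 rose (adjusted p = 0.07; 9 and 4 adjusted over the list alone). The histone deacetylase Hdac1 rose by 1.39 (1.37 on its other probe set), and Rbbp4 and Uhrf1 fell by 0.62 and 0.61.

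The Polycomb subunit Ezh2 was not called in untreated cells (-0.13, adjusted p = 0.473). Suz12 was called at -0.48 (adjusted p = 0.0125), but not without siControl replicate 1 (-0.38, adjusted p = 0.0652), siSox4 replicate 1 (-0.52, adjusted p = 0.068) or siSox4 replicate 2 (-0.45, adjusted p = 0.0956). Eed was called at 0.58 (adjusted p = 0.0214), but not without siControl replicate 2 (0.42, adjusted p = 0.112), siSox4 replicate 1 (0.48, adjusted p = 0.165) or siSox4 replicate 2 (0.68, adjusted p = 0.0569). Taking the mean of all probe sets of Eed also ended the call (0.29, adjusted p = 0.0977), as its dimmer probe set gave 0.01, and so did testing every probe set (adjusted p = 0.083).

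Unfolded protein and amino acid stress genes gave 5 falls and 1 rise of 26 (adjusted p = 0.119; 6 and 2 adjusted over the list alone), with Ddit4 at -0.87 and Herpud1 at -0.66. P53 target and apoptosis genes gave 8 rises and 3 falls of 30 (adjusted p = 0.496; 10 and 5 adjusted over the list alone), with the pro-apoptotic genes Pmaip1 at 0.59, Bmf at -1.03 and Bcl2l11 at -0.71. The Notch, Hedgehog and EGFR ligand list gave 4 rises and 4 falls of 32 (adjusted p = 0.861; 6 and 4 adjusted over the list alone), with Ereg at 1.16, Jag1 at 0.98 and Smo at -0.78. Its test pointed up and its mean was 0.05, while its median was -0.03. Wnt pathway genes gave 4 rises and 1 fall of 29 (adjusted p = 0.861, same counts adjusted over the list alone), with Fzd2 at -0.94 and Wnt4 at 0.65. Oxidative phosphorylation genes (2 rose and 1 fell of 27; 1 and 1 adjusted over the list alone; adjusted p = 0.72), ribosomal protein genes (0 of 22, adjusted p = 0.903) and the 14 Sox family genes other than Sox4 (0 called, adjusted p = 0.459) were also not called. The marker lists of luminal, basal, fibroblast, endothelial, leukocyte and neuronal cells had adjusted p between 0.496 and 0.861.

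In all, limma called 2466 of 19937 genes at an adjusted p of 0.05 in untreated cells, 1222 higher and 1244 lower in siSox4, and 4702 genes had an unadjusted p under 0.05. A change of at least 2-fold was seen in 176 of the called genes, 109 higher and 67 lower. The count was sensitive to single arrays: it was 1589 without siControl replicate 2, 919 without siSox4 replicate 1 and 1092 without siSox4 replicate 2, and 1623 when every probe set was tested on its own.

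**Figure D2:**
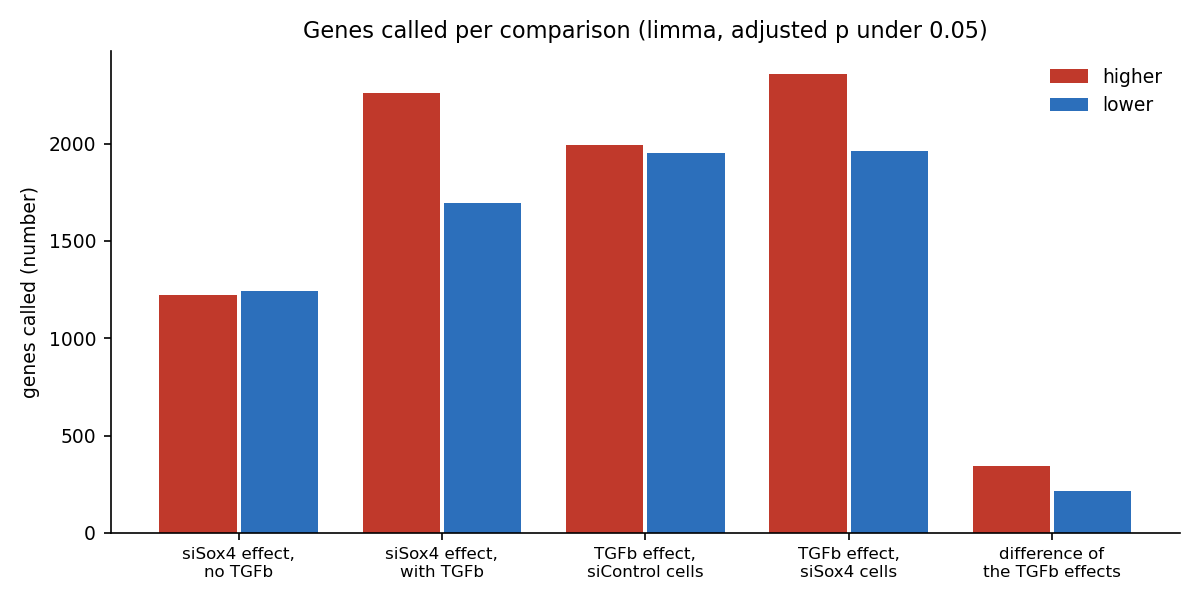
Number of genes called by limma (y axis) in each of the 5 comparisons (x axis), with higher genes in red and lower genes in blue. The difference of the TGFβ effects has the fewest, 345 higher and 213 lower, and the siSox4 comparison with TGFβ has 2259 higher and 1693 lower.

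The same comparison in TGFβ-treated cells asks which genes depend on Sox4 while cells respond to the growth factor. The largest rise with siSox4 was that of Sprr2h, a cornified envelope protein of a family of close copies, at 4.65 (SE 0.19, adjusted p = 3.26e-06). The chemokine Ccl9 rose by 3.54 (SE 0.16), Bpifc by 3.23, Prl2c5 (also one of several close copies) by 3.19 and Clrn3 by 3.06. Cdhr5, a cadherin of brush border microvilli, rose by 3.28 (SE 0.09, adjusted p = 1.32e-06). The largest falls were Tead2 at -2.69 (SE 0.09, adjusted p = 1.63e-06), the RNA-binding protein Mex3a at -2.57, the adhesion molecule Mcam at -2.49, Igsf9 at -2.47, Pate14 at -2.46 and Ccnd2 at -2.43. Pate14 had a signal of only 3.76 and 3.89 in siSox4 cells with TGFβ, not shown to be above background, so the size of its fall is uncertain. The same limit holds for the rise of Prl2c5, which had 4.33 and 3.63 in siControl cells with TGFβ. All 12 were called without any single array.

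Contractile and adhesion genes were lower in siSox4 cells with TGFβ. Of 30 actin cytoskeleton and focal adhesion genes 12 fell and 2 rose (adjusted over the list alone, 14 and 2), with a median of -0.19. Palld, an actin-bundling protein, fell by 1.68, Cnn2 (calponin 2) by 1.33 and Csrp1 by 0.96, while Itga2 rose by 1.79. Camera called this list (adjusted p = 0.00204), and the call was lost with an estimated correlation (adjusted p = 0.375). Mesenchymal and EMT genes gave 11 falls and 5 rises of 34 (13 and 5 adjusted over the list alone) and were not called by camera (adjusted p = 0.101). The alternative fry, which does not compare a list with other genes, called them lower (adjusted p = 0.00356). Smooth muscle actin (Acta2) fell by 1.79 (SE 0.15, adjusted p = 8.86e-05), Tagln by 1.61 and Tnc by 1.87. Itga5 fell by 0.98, Zeb2 by 0.76 (adjusted p = 0.00176) and Fn1 by 0.50 (adjusted p = 0.00329). In siSox4 cells with TGFβ the signal was only 5.17 and 4.91 for Acta2 and 4.67 and 4.54 for Tagln. These signals were not shown to be above background, so the sizes of both falls are uncertain.

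Other EMT genes named in advance did not pass: Cdh1 was at -0.11, Cdh2 at -0.23, Ncam1 at -0.31 (adjusted p = 0.0638), Vim at -0.03 and Smad7 at 0.12. Snai1, a repressor of Cdh1, was called higher at 0.75 (adjusted p = 0.00898), but not without siSox4 with TGFβ replicate 1 (0.66, adjusted p = 0.0697). Id1 was called at 0.48 (adjusted p = 0.0118), but not without siSox4 with TGFβ replicate 2 (0.41, adjusted p = 0.0994). Zeb1, called at 0.35 (adjusted p = 0.044), lost the call without any of the 4 arrays with TGFβ, at 0.36 and 0.34 without siControl replicates 1 and 2 and at 0.31 and 0.38 without siSox4 replicates 1 and 2 (adjusted p up to 0.197).

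The fall of replication and division genes was also seen with TGFβ. S phase and DNA replication genes gave 20 falls and 2 rises of 34 (26 and 2 adjusted over the list alone), with a median of -0.34, including Chaf1b at -0.96, Mcm7 at -0.79 and Cdc6 at -0.51, while Ccne1 rose by 0.54. Camera gave adjusted p = 4.66e-07, and with an estimated correlation the list was not called (adjusted p = 0.507). Mitosis genes gave 7 falls of 34 and no rise (11 adjusted over the list alone), with Bub1 at -0.67 and Kif20a at -0.51 (camera, adjusted p = 0.00202; 0.638 with an estimated correlation). That call was also lost without siControl with TGFβ replicate 1 (median -0.11, adjusted p = 0.0994) and in the fry test (adjusted p = 0.0598).

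Inflammatory genes were higher again, with 10 of 26 rising and 1 falling (11 and 2 adjusted over the list alone). The adhesion molecule Vcam1 rose by 2.94 (SE 0.19, adjusted p = 2.56e-05), Ccl20 by 1.92, the NF-kB inhibitor Nfkbia by 1.22 and Nfkb2 by 0.69. The list passed camera (adjusted p = 0.00666) and lost the call with an estimated correlation (adjusted p = 0.367). Of 27 oxidative phosphorylation genes 7 rose and 1 fell (same counts adjusted over the list alone), with Cox7a2 at 0.57, Sdhb at 0.53 and Sdhd at -0.64 (adjusted p = 0.00202). This call was lost with an estimated correlation (adjusted p = 0.365) and without the dimmest genes (adjusted p = 0.122). Of 30 interferon response genes 5 rose and 1 fell (same counts adjusted over the list alone), and the list was not called (adjusted p = 0.775), with its median at -0.08 and its mean at 0.02.

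Among epithelial genes, 9 of 37 adhesion and junction genes rose and 5 fell (adjusted p = 0.569; 10 and 6 adjusted over the list alone), with the transcription factor Elf3 at 1.22 and the desmosomal cadherin Dsg2 at 0.99. Keratins and cornified epithelium genes gave 3 rises and 3 falls of 21 (adjusted p = 0.842, same counts adjusted over the list alone), with Sprr1a at 2.82, Perp at 2.13 and Krt7 at -0.71. Extracellular matrix genes gave 4 rises and 5 falls of 35 (adjusted p = 0.651; 4 and 7 adjusted over the list alone), with Mmp13 at 2.43, Lamb3 at 1.52, Fbln1 at -1.04 and Col1a1 at -0.80. In these 3 lists and the interferon list the median and the mean differed in sign. TGFβ and SMAD target genes gave 6 rises and 5 falls of 29 (adjusted p = 0.322; 7 and 6 adjusted over the list alone), with the SMAD-induced inhibitor Id3 at -1.30, Klf10 at 1.13 and Ccn1 at -0.82.

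Polycomb and chromatin repressor genes gave 10 falls and 8 rises of 29 (adjusted p = 0.336; 12 and 8 adjusted over the list alone). Hdac1 rose by 1.08, Cbx2 fell by 0.73, and Rbbp4 and Mtf2 each fell by 0.66. Ezh2, the H3K27 methyltransferase, was called at -0.48 (SE 0.09, adjusted p = 0.00646), but not without siSox4 with TGFβ replicate 2 (-0.43, adjusted p = 0.0618). Suz12 was called at -0.42 (adjusted p = 0.0153), but not without siControl with TGFβ replicate 1 (-0.36, adjusted p = 0.0677), siSox4 with TGFβ replicate 1 (-0.45, adjusted p = 0.0654) or its replicate 2 (-0.39, adjusted p = 0.104), nor after median centring (-0.31, adjusted p = 0.0925). Eed was called at 0.64 (adjusted p = 0.00932), but not without siControl with TGFβ replicate 2 (0.51, adjusted p = 0.0623), siSox4 with TGFβ replicate 1 (0.63, adjusted p = 0.0567) or its replicate 2 (0.64, adjusted p = 0.055). The dimmer probe set of Eed gave -0.05, and the mean of its probe sets 0.30 (adjusted p = 0.0679).

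The remaining lists did not pass with TGFβ. Among signalling genes, Wnt7a fell by 1.82, Etv4 by 1.49 and Smo by 0.88, while the EGFR ligand Ereg rose by 1.79; the Notch, Hedgehog and EGFR ligand list (8 rose and 5 fell of 32; 10 and 7 adjusted over the list alone; median -0.05, mean 0.01) had adjusted p = 0.842 and the Wnt list (3 rose and 3 fell of 29; 4 and 5 over the list alone) 0.299. Acly fell by 1.39 and Hmgcs1 rose by 0.76 in the sterol and fatty acid list (6 rose and 4 fell of 21, 6 and 5 over the list alone, adjusted p = 0.595, median 0.10 against a mean of -0.02). The death receptor Fas rose by 1.76 and Casp12 fell by 0.95 in the p53 and apoptosis list (8 rose and 5 fell of 30, 11 and 8 over the list alone, adjusted p = 0.299). Casp12 had a signal of only 3.38 and 3.36 in siSox4 cells with TGFβ, not shown to be above background, so the size of its fall is uncertain. Stress genes (4 rose and 4 fell of 26, 6 and 5 over the list alone, adjusted p = 0.454), ribosomal protein genes (1 rose of 22, 0 over the list alone, adjusted p = 0.145) and Sox family genes (2 rose and 1 fell of 14, 2 and 2 over the list alone, adjusted p = 0.595; Sox9 at 0.79 and Sox6 at 0.69) were not called. The marker lists of other cell types had adjusted p between 0.119 and 0.842.

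With TGFβ, limma called 3952 genes, 2259 higher and 1693 lower in siSox4, and 6328 had an unadjusted p under 0.05. Of these, 395 changed at least 2-fold, 256 higher and 139 lower. Centring each array on its median moved the median of all genes from -0.04 to 0.08 and the share of higher calls from 57.2% to 77.8% (4342 calls), so the balance of rises and falls depends on the scaling, while camera compares a list with all other genes. The count was 2172 without siSox4 with TGFβ replicate 1 and 2048 without its replicate 2.

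Both siSox4 comparisons shared many calls. Higher in both were 830 genes, against 138 for independent lists, and lower in both were 703, against 106. Their log2 fold changes correlated across genes (Pearson r = 0.56, Spearman rho = 0.38 over 19937 genes, which are not independent replicates), and they use different arrays. Opposite calls were made for 45 genes, among them Tnc (1.16 without and -1.87 with TGFβ) and Thbs1 (1.42 and -0.30, adjusted p = 0.0496 for the latter). The 1533 shared calls fell to 690 without siSox4 replicate 1, 756 without its replicate 2, 930 without siSox4 with TGFβ replicate 1 and 942 without its replicate 2, and were 941 when every probe set was tested.

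The response to TGFβ in siControl cells is the reference for the effect of Sox4 on it. Tenascin C (Tnc) rose most, by 4.84 (SE 0.15, adjusted p = 3.68e-07), followed by the cytokine Il11 at 4.24, Ctsw at 4.22, the syndecan Sdc3 at 3.66, the fibronectin receptor subunit Itga5 at 3.65 and Thbs1 at 3.51. The largest falls were in enzymes of small-molecule metabolism: Cyp2c65 at -3.83, Cyp2s1 at -3.57, Mettl7b at -3.50, Ugt2b34 at -3.44 and Akr1c19 at -3.40, with the brush border protease Mep1a at -3.64 (SE 0.10, adjusted p = 2.82e-07). Cyp2c65, Ugt2b34 and Akr1c19 belong to families of near-identical genes, so their values are uncertain as to the copy. In siControl cells with TGFβ the signal was only 4.49 and 4.44 for Mep1a and 4.35 and 4.71 for Cyp2c65. It was 4.69 and 4.88 for Ugt2b34 and 5.07 and 4.68 for Akr1c19. In untreated siControl cells it was 4.67 and 4.93 for Sdc3, 4.50 and 5.05 for Il11 and 5.29 and 4.78 for Tnc. Such signals were not shown to be above background, so the sizes of these falls and rises are uncertain. All 12 were called without any single array.

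TGFβ raised mesenchymal, contractile and SMAD target genes in siControl cells. Of 34 mesenchymal and EMT genes 17 rose and none fell (same counts adjusted over the list alone), with Fn1 at 2.69 (SE 0.08), Itgb3 at 2.50, Acta2 at 1.78, Ncam1 at 1.72, Zeb2 at 1.59, Snai1 at 1.24, Zeb1 at 1.20 and Cdh2 at 0.96. Of 30 actin cytoskeleton and focal adhesion genes 20 rose and 2 fell (21 and 2 adjusted over the list alone), with Actn1 at 1.91, Cald1 at 1.79 and Rhob at 1.68. Of 29 TGFβ and SMAD target genes 21 rose and 2 fell (23 and 2 adjusted over the list alone), with Ltbp1 at 2.41, Ccn2 at 1.71, Cdkn2b at 1.62 and Smad7 at 1.45. Camera gave adjusted p = 6.2e-09, 1.16e-13 and 2.6e-13 for these lists, and all 3 held with an estimated correlation (adjusted p = 0.0444 for each). Acta2 had only 4.99 and 5.12 in untreated siControl cells, not shown to be above background, so the size of its rise is uncertain. Id1 fell by 0.93. Vim was called at 0.32 (adjusted p = 0.0162), but not without siControl replicate 2 (0.30, adjusted p = 0.067) or siControl with TGFβ replicate 1 (0.30, adjusted p = 0.0581).

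Division genes fell almost as a whole. All 34 mitosis genes fell (34 adjusted over the list alone), with a median of -0.79, including Kif11 at -1.09, Aurkb at -1.03 and survivin (Birc5) at -0.96. Of 34 S phase and DNA replication genes 32 fell and none rose (33 adjusted over the list alone), with Mcm10 at -1.03 and Tk1 at -0.96. Camera gave adjusted p = 1.12e-23 and 1.41e-20, and neither list was called with an estimated correlation (adjusted p = 0.0943 for each). Sterol and fatty acid synthesis genes gave 14 falls of 21 and no rise (16 and 1 adjusted over the list alone), with the lanosterol synthase Lss at -1.22 and Hmgcs1 at -0.99 (adjusted p = 2.6e-08; 0.162 with an estimated correlation). Oxidative phosphorylation genes gave 6 falls of 27 and no rise (8 adjusted over the list alone), such as Sdhd at -0.44 (adjusted p = 0.000169; 0.066 with an estimated correlation).

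Matrix, stress and Wnt genes passed with more limits. Of 35 extracellular matrix genes 15 rose and 2 fell (same counts adjusted over the list alone), with fibulin 2 (Fbln2) at 3.04, Col12a1 at 1.74, the membrane protease Mmp14 at 1.70 and Mmp13 at -1.98 (adjusted p = 6.42e-06; 0.174 with an estimated correlation). Unfolded protein and amino acid stress genes gave 12 falls and 5 rises of 26 (14 and 5 adjusted over the list alone), with Ero1a at -1.23, the cystine carrier Slc7a11 at -1.20 and Ddit4 at 0.91 (adjusted p = 0.00649; 0.174 with an estimated correlation). That call was lost without siControl replicate 1 (median -0.24, adjusted p = 0.0533), siControl with TGFβ replicate 2 (median -0.28, adjusted p = 0.0517) or the dimmest genes (adjusted p = 0.0639). Wnt pathway genes gave 7 rises and 1 fall of 29 (9 and 1 adjusted over the list alone), led by Wnt7a at 3.44 and Porcn, which acylates Wnt proteins, at 1.52 (adjusted p = 0.0422; 0.561 with an estimated correlation). Their median of 0.05 became -0.04 without siControl replicate 1 (adjusted p = 0.256) and without siControl with TGFβ replicate 2 (adjusted p = 0.129).

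Epithelial genes went both ways in siControl cells, with 13 falls and 7 rises of 37 (adjusted p = 0.204, same counts adjusted over the list alone). The transcription factors Ehf and Klf5 fell by 1.55 and 1.03 and the polarity gene Crb3 by 0.83, while claudin 4 (Cldn4) rose by 3.02. Cdh1 was at -0.17 (SE 0.10, adjusted p = 0.302) and was not called. Keratins and cornified epithelium genes gave 7 falls and 5 rises of 21 (7 and 6 over the list alone, adjusted p = 0.586), with Sprr1a at -1.43 and Krt7 at 1.12. Inflammatory genes gave 7 rises and 4 falls of 26 (8 and 4 over the list alone, adjusted p = 0.132), with Ccl20 at -3.10, Csf1 at 1.96 and Csf2 at 1.85. Polycomb genes gave 3 rises and 3 falls of 29 (4 and 4 over the list alone, adjusted p = 0.714), with Suz12 at -0.53 (adjusted p = 0.00399), Ezh2 at -0.29 (adjusted p = 0.0553) and Eed at -0.02.

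Also not called in this comparison were the p53 and apoptosis list (9 rose and 3 fell of 30, the same over the list alone, Bcl2l11 at 1.29, adjusted p = 0.132), the Notch, Hedgehog and EGFR ligand list (9 rose and 7 fell of 32, 9 and 8 over the list alone, Jag1 at 1.69 and Erbb3 at -1.45, adjusted p = 0.586) and the interferon list (2 rose and 4 fell of 30, the same over the list alone, Oasl2 at 1.73, adjusted p = 0.943, tested as lower while its median was 0.01). Ribosomal protein genes (0 of 22, adjusted p = 0.132) and Sox family genes (1 rose and 1 fell of 14, adjusted p = 0.452) did not pass either. The marker lists had adjusted p between 0.0782, for neuronal markers, and 0.613. Over all genes, limma called 3946, 1992 higher and 1954 lower with TGFβ, while 5724 had an unadjusted p under 0.05. Of the called genes, 665 changed at least 2-fold (361 higher and 304 lower). Fitting only the 4 siControl arrays gave 2834 calls, and array weights gave 3211.

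The same treatment in siSox4 cells shows the response that remained after the Sox4 siRNA. Ctsw rose by 4.51, the actin-capping protein Capg by 4.03 (SE 0.10, adjusted p = 1.98e-07), Sdc3 by 3.90, Ctla2a by 3.78, Cyp21a1 by 3.57 and Orm3 by 3.39. Cyp4a12b fell by 5.51 (SE 0.14, adjusted p = 1.98e-07), Cyp4a12a by 4.51, Ugt2b36 by 3.90, Cyp2s1 by 3.83, the retinal dehydrogenase Aldh1a1 by 3.46 and the alarmin Il33 by 3.46. Of these, Ctla2a, Orm3, Ugt2b36 and both Cyp4a12 genes have close copies. The low side of the comparison was 3.31 and 3.95 for Ugt2b36, 3.75 and 3.79 for Cyp4a12a, and 3.96 and 4.25 for Cyp4a12b. It was 3.83 and 3.15 for Ctla2a, 4.45 and 4.42 for Sdc3 and 4.81 and 4.79 for Orm3. Signals this low were not shown to be above background, so the sizes of these changes are uncertain. All 12 were called without any single array.

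Mesenchymal and EMT genes gave 13 rises and 1 fall of 34 in siSox4 cells (13 and 2 adjusted over the list alone), with Fn1 at 3.10 (SE 0.08), Itga5 at 3.15, Ncam1 at 2.08, Snai1 at 2.07, Zeb2 at 1.17, Zeb1 at 1.05 and Cdh2 at 0.56 (adjusted p = 0.00148). Actin cytoskeleton and focal adhesion genes gave 20 rises and 3 falls of 30 (20 and 5 adjusted over the list alone), with Rhob at 1.95 and Cald1 at 1.40. TGFβ and SMAD target genes gave 18 rises and 3 falls of 29 (same counts adjusted over the list alone), with Ltbp1 at 2.18, Smad7 at 1.80 and the receptor Tgfbr1 at 1.55. Camera gave adjusted p = 0.000273, 9.53e-08 and 2.66e-10 for these lists, and none was called with an estimated correlation (adjusted p = 0.119 for each). Id1 fell by 0.73. Cdh1 was at -0.13 (adjusted p = 0.38). Vim, called at 0.25 (adjusted p = 0.045), lost the call without any of the 4 siSox4 arrays, with values from 0.24 to 0.26 (adjusted p from 0.148 to 0.203).

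Division genes fell in siSox4 cells too: 32 of 34 mitosis genes (32 adjusted over the list alone; adjusted p = 2.46e-17), with Ect2 at -1.10, and 27 of 34 S phase and DNA replication genes (28 adjusted over the list alone; adjusted p = 1.2e-14), with Rrm2 at -0.93. Both calls were lost with an estimated correlation (adjusted p = 0.185 for each). Extracellular matrix genes gave 13 rises and 3 falls of 35 (16 and 7 adjusted over the list alone; adjusted p = 0.0102), with Lamb3 at 1.82 and Mmp14 at 1.80, and lost the call with an estimated correlation (adjusted p = 0.53) and without the dimmest genes (adjusted p = 0.0642). Sterol and fatty acid genes gave 8 falls of 21 and no rise (9 adjusted over the list alone), with Elovl6 at -1.23 (adjusted p = 0.0102; 0.596 with an estimated correlation). P53 target and apoptosis genes gave 10 rises and 2 falls of 30 (10 and 3 adjusted over the list alone), with Bmf at 1.26 and Gadd45a at 0.73 (adjusted p = 0.011). With an estimated correlation that list was not called (adjusted p = 0.185), nor without the dimmest genes (adjusted p = 0.0933).

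Ezh2 fell by 0.63 in siSox4 cells with TGFβ (SE 0.09, adjusted p = 0.00103), whereas its fall in siControl cells had not passed, and the difference between these effects, -0.34 (SE 0.13), was not called (adjusted p = 0.213). Suz12 was called at -0.47 (adjusted p = 0.00769), but not without siSox4 replicate 1 (-0.44, adjusted p = 0.0644) or siSox4 with TGFβ replicate 2 (-0.44, adjusted p = 0.0638). The de novo DNA methyltransferase Dnmt3a rose by 1.03 and Uhrf1 fell by 0.85, with 5 falls and 2 rises among 29 Polycomb and chromatin repressor genes (adjusted p = 0.837).

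None of the other lists passed in this comparison. The lowest adjusted p was 0.0515, for inflammatory genes (10 rose and 4 fell of 26, 11 and 4 over the list alone, Ccl20 at -2.75 and Ccl7 at 1.87). Epithelial adhesion genes gave 12 falls and 8 rises of 37 (13 and 8 over the list alone, adjusted p = 0.547), and keratins 7 falls and 2 rises of 21 (7 and 3 over the list alone, adjusted p = 0.577), with Krt19 at -1.61 and Ppl at -1.92. Stress genes gave 10 falls and 5 rises of 26 (10 and 7 over the list alone, adjusted p = 0.577), with Ddit4 at 1.63. Interferon genes (5 rose and 2 fell of 30; median -0.05, mean 0.05), oxidative phosphorylation genes (1 rose and 2 fell of 27) and Sox family genes (1 rose and 2 fell of 14) had adjusted p = 0.577 too, with the same counts over each list alone, and Sox9 rose by 1.55. The Notch, Hedgehog and EGFR ligand list had 7 rises and 9 falls of 32 (8 and 10 over the list alone, adjusted p = 0.741; median 0.01, mean -0.01), and ribosomal protein genes 0 calls of 22 (adjusted p = 0.837). Wnt genes gave 6 rises and 2 falls of 29 (adjusted p = 0.547), with Wnt7a at 1.58 and Fzd1 at 1.40, and their median, -0.07, and mean, 0.14, differed in sign. The marker lists had adjusted p between 0.228 and 0.833. Limma called 4323 genes, 2360 higher and 1963 lower, with 6625 at an unadjusted p under 0.05 and 634 changed at least 2-fold (408 higher and 226 lower). Fitting only the 4 siSox4 arrays gave 5583 calls, and array weights gave 5935. Median centring gave 4306 calls with 69.0% higher, against 54.6% as reported. The count was 2727 without siSox4 replicate 1, 2707 without its replicate 2, 2834 without siSox4 with TGFβ replicate 1 and 2594 without its replicate 2.

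Most of the TGFβ response was shared by siControl and siSox4 cells. Higher in both were 1386 genes, against 236 for independent lists, and lower in both were 1146, against 192 (Pearson r = 0.74, Spearman rho = 0.49 across genes). Over 5525 genes with a called mean TGFβ effect, the median ratio of the effect in siSox4 to that in siControl cells was 0.996 (quartiles 0.614 and 1.58), and it was smaller in siSox4 cells for 2681 genes, or 48.5%. This median pools both sides: the ratio was 1.13 for the 2904 genes that TGFβ raised (smaller in siSox4 cells for 41.0%) and 0.878 for the 2621 it lowered (smaller for 56.8%). The sides were split for the deposited scaling only. A common positive offset of the differences would also part these ratios, and median centring moved the median difference of all genes from -0.03 to 0.07. Fry, which asks whether genes move on balance one way, called no difference over the 5525 genes or on either side. It called one without siControl with TGFβ replicate 1 (ratio 0.938) and without replicate 2 of both siControl groups (ratio 0.949). By list, the median ratio was 0.705 for the 24 actin and adhesion genes with a called mean effect, 0.785 for 17 mesenchymal genes, 0.902 for 24 SMAD target genes, 0.894 for 34 mitosis genes, 0.988 for 19 matrix genes and 0.544 for 14 sterol and fatty acid genes.

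**Figure D3:**
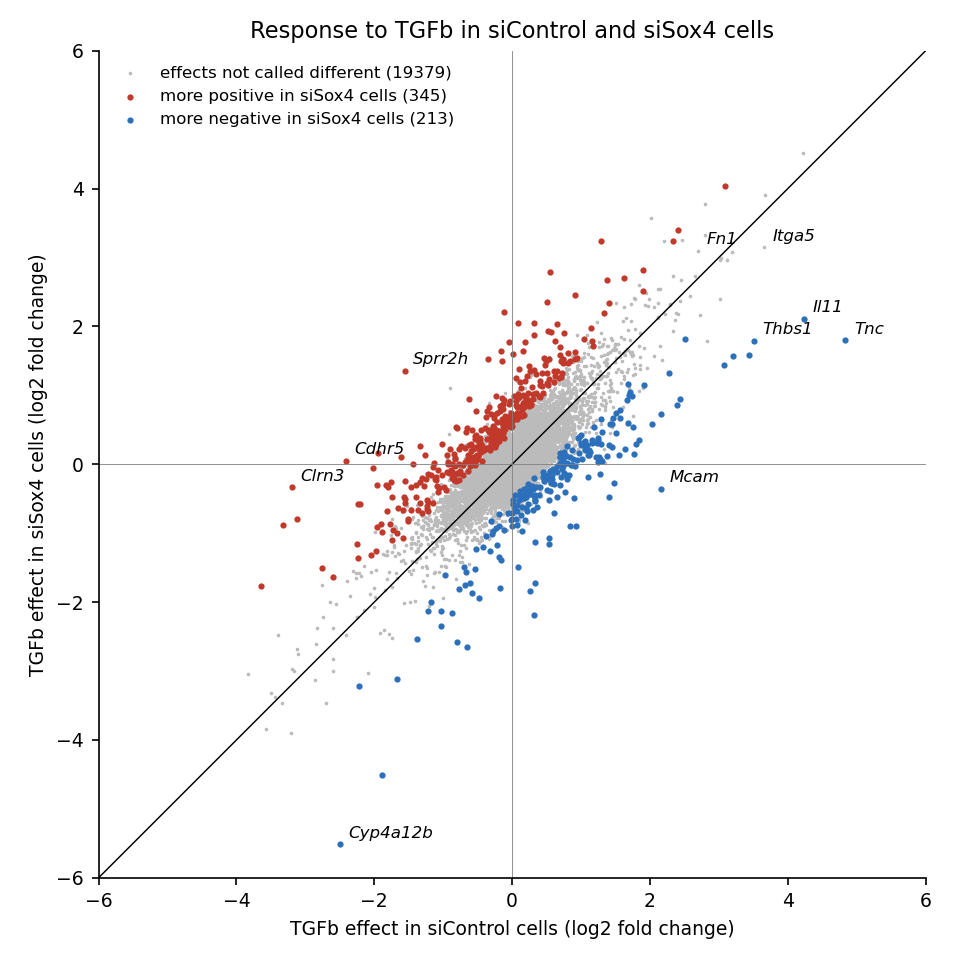
Log2 fold change with TGFβ in siControl cells (x axis) against that in siSox4 cells (y axis) for 19937 genes (points). Genes with a more positive TGFβ effect in siSox4 cells by the limma test are red (345), those with a more negative effect blue (213) and the rest grey, and most points lie along the diagonal.

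A test of the difference between the TGFβ effects asks which parts of the response depend on Sox4. Tnc had the largest loss, with a TGFβ effect lower by 3.04 in siSox4 cells (that is, -3.04, SE 0.22, adjusted p = 0.000413), a rise of 4.84 in siControl and of 1.80 in siSox4 cells. Mcam differed by -2.51 (SE 0.14, adjusted p = 0.000194), Thbs1 by -1.72 (adjusted p = 0.000638), Id3 by -1.69 (adjusted p = 0.00329) and Acta2 by -1.63 (adjusted p = 0.0068). The Thbs1 difference came mainly from its rise of 1.42 with siSox4 in untreated cells, as its change with siSox4 was only -0.30 with TGFβ. The cytokine Il11 differed by -2.13 (adjusted p = 0.0103), but was not called without siSox4 replicate 1 (-2.13, adjusted p = 0.0649) or its replicate 2 (-2.13, adjusted p = 0.0585). Gbp9 differed by -2.10. Acta2 had signals of only 4.78 to 5.17 outside siControl cells with TGFβ. These were not shown to be above background, so the size of its difference is uncertain. Cyp4a12b and Cyp4a12a, higher in siSox4 cells only before treatment, differed by -3.01 and -2.62. Their signals with TGFβ lay between 3.68 and 4.63 in all 4 arrays, not shown to be above background, so these differences may only repeat the rise with siSox4 in untreated cells. In the other direction, Sprr2h (2.91), Clrn3 (2.86, SE 0.13, adjusted p = 0.000145), Cdhr5 (2.46), the galectin Lgals4 (2.44), the serpin Serpinb5 (2.33), Vsig1 (2.32) and Sprr1a (1.44) had a more positive TGFβ effect in siSox4 cells. TGFβ lowered Clrn3 by 3.19 in siControl cells and by 0.33 in siSox4 cells, and Lgals4 by 3.33 and 0.89. Serpinb5 had a signal of only 3.38 to 3.54 in the 6 arrays outside siSox4 with TGFβ, where it was not shown to be above background, so the size of its difference is uncertain.

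By list, actin cytoskeleton and focal adhesion genes had a lower TGFβ effect in siSox4 cells, with a median of -0.31, 6 of 30 called lower and none higher (13 adjusted over the list alone; camera adjusted p = 7.58e-06), and the call was lost with an estimated correlation (adjusted p = 0.227). Sterol and fatty acid synthesis genes had a median of 0.27, which is a weaker fall, with 1 of 21 called (4 adjusted over the list alone; adjusted p = 0.000425, and 0.458 with an estimated correlation). Mesenchymal and EMT genes had 7 of 34 called lower and none higher (9 and 2 adjusted over the list alone; adjusted p = 0.0198). Their call was lost with an estimated correlation (adjusted p = 0.227), without siControl with TGFβ replicate 1 (median -0.18, adjusted p = 0.0531) and without the dimmest genes (adjusted p = 0.0539). No gene of the set named in advance for EMT and Polycomb differed: Fn1 was at 0.40 (adjusted p = 0.12), Cdh2 at -0.40 (adjusted p = 0.13), Snai1 at 0.83 (adjusted p = 0.0932), Zeb2 at -0.41 (adjusted p = 0.226) and Cdh1 at 0.04 (adjusted p = 0.916). TGFβ and SMAD target genes as a list were not called, with 4 lower and 2 higher of 29 (6 and 6 over the list alone, adjusted p = 0.613).

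Of the other lists, 4 passed camera for this difference, and none of them with an estimated correlation. Unfolded protein and amino acid stress genes had 4 of 26 called with a more positive TGFβ effect (8 and 2 lower over the list alone; median 0.14, adjusted p = 0.0208, and 0.458 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.11 with 0 of 27 called (adjusted p = 0.0124; 0.227 with an estimated correlation). Fibroblast markers had 2 of 14 called lower (median -0.21, adjusted p = 0.033; 0.682 with an estimated correlation) and endothelial markers 1 of 14 (2 over the list alone; median -0.18, adjusted p = 0.033; 0.671 with an estimated correlation). Without siControl replicate 1 these 4 lists had adjusted p = 0.127, 0.0676, 0.195 and 0.127, and without siControl with TGFβ replicate 2 they had 0.0686, 0.0594, 0.0686 and 0.0686. Without siSox4 replicate 1 the fibroblast and endothelial markers had 0.0777 and 0.0927, and without siSox4 with TGFβ replicate 1 each had 0.0551. Without the dimmest genes the stress and oxidative phosphorylation lists had 0.423 and 0.237, and with fry the fibroblast and endothelial markers had 0.245 and 0.118. Without the dimmest genes only Flt1 was left of the endothelial markers, and their median turned positive. Some of these markers were dim, such as Plvap at 3.70 to 4.17. Random lists matched on brightness were drawn only for S phase and mitosis genes, so an effect of brightness on the marker lists was not tested. Matrix genes had 5 lower and 1 higher of 35 (6 and 1 over the list alone, adjusted p = 0.112), mitosis genes 0 of 34 (adjusted p = 0.112) and S phase genes 1 higher of 34 (adjusted p = 0.332). The epithelial list had 1 higher of 37 (2 over the list alone, adjusted p = 0.416), keratins 2 higher and 1 lower of 21 (3 and 6, adjusted p = 0.627) and inflammatory genes 1 higher of 26 (4 and 5, adjusted p = 0.613; median -0.03, mean 0.13). Adjusted p was 0.142 for Wnt and ribosomal protein genes, 0.261 for Sox family, 0.456 for p53 and apoptosis, 0.561 for interferon, 0.891 for Notch, Hedgehog and EGFR ligand and 0.988 for Polycomb genes.

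Limma called 558 genes for this difference, 345 with a more positive and 213 with a more negative TGFβ effect in siSox4 cells, while 3439 had an unadjusted p under 0.05, and 155 differed at least 2-fold (91 and 64). Median centring gave 769 calls and moved the share of positive ones from 61.8% to 77.6%, with the median of all genes going from -0.03 to 0.07. The count was 334 without siControl replicate 1, 109 and 129 without siSox4 replicates 1 and 2, 288 without siControl with TGFβ replicate 2, and 193 and 148 without siSox4 with TGFβ replicates 1 and 2. Of the 45 named genes called here, 15 were called without every single array in turn, among them 11 of the 12 largest. Acta2 lost its call when every probe set was tested on its own (adjusted p = 0.0714).

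**Figure D4:**
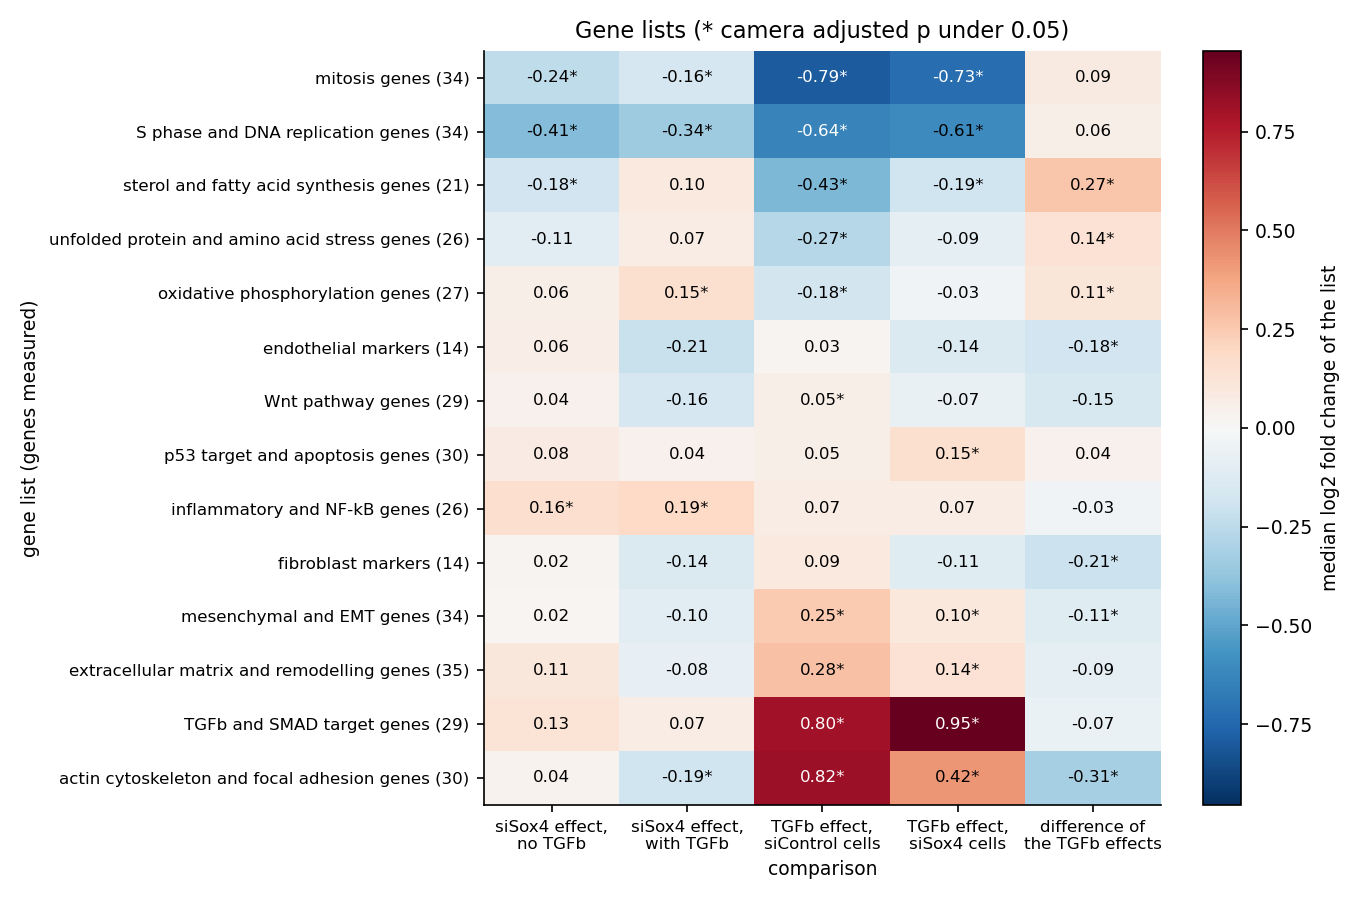
Median log2 fold change of gene lists (rows) in the 5 comparisons (columns), for the lists called by camera in at least 1 comparison, coloured from blue (lower) to red (higher), with stars for adjusted p under 0.05. Mitosis genes fell most with TGFβ, at a median of -0.79 in siControl cells and -0.73 in siSox4 cells.

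Many genes that TGFβ changed in siControl cells were moved the opposite way by siSox4 in TGFβ-treated cells. Of the genes raised by TGFβ, 589 were lower in siSox4 cells with TGFβ, against 169 for independent lists (Fisher's exact test, one-sided, p = 5.09e-192). Of those lowered by TGFβ, 736 were higher, against 221 (Fisher's exact test, one-sided, p = 2.23e-234), giving 1325 opposite calls beside 570 of the same sign. Genes are not independent replicates, and both comparisons use the same 2 siControl arrays with TGFβ, which alone gives a negative correlation. In 100 simulations of unchanged groups the mean r was -0.50, with a covariance of -0.0064 and 0 opposite calls, whereas the observed r was -0.30, with a covariance of -0.0413, lower by 0.0349 (a difference of -0.0349). No gene was changed in these simulations, so opposite calls were hardly possible there. The 0 therefore cannot show how many of the 1325 opposite calls the shared arrays make. Part of the excess may come from the shared arrays, which are too few to split. For siSox4 without TGFβ, 629 calls were opposite to the TGFβ change and 616 of the same sign (Pearson r = -0.017, Spearman rho = 0.11). Here the 2 shared siControl arrays would instead give a positive correlation. The count of 1325 was 823 without siSox4 with TGFβ replicate 1 and 779 without its replicate 2.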

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

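The results here were marked because the TGFβ effect differed between siSox4 and siControl cells by a test of that difference itself. Tests of weaker exposure, of the normalization, of the number-2 arrays and of interferon genes were chosen only after the result was seen, while those of brightness and signal range were written before.

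The difference was called for 558 genes (limma, adjusted p under 0.05). Of the 45 named genes among them, 15 were called without each array in turn: Tnc (-3.04), Cyp4a12b (-3.01), Cyp4a12a (-2.62), Mcam (-2.51), Gbp9 (-2.10), Thbs1 (-1.72), Id3 (-1.69) and Acta2 (-1.63) with a more negative effect, and Sprr2h (2.91), Clrn3 (2.86), Cdhr5 (2.46), Lgals4 (2.44), Serpinb5 (2.33), Vsig1 (2.32) and Sprr1a (1.44) with a more positive one. For both Cyp4a12 genes the signals with TGFβ, and for Serpinb5 those in the other groups, were not shown to be above background. Acta2 had signals of only 4.78 to 5.17 outside siControl cells with TGFβ, with the same limit. The sizes of these differences are therefore uncertain. That of the Cyp4a12 genes shows no TGFβ response that depends on Sox4 beyond their rise in untreated siSox4 cells. The other 30 lost the call without at least 1 array.

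Among those 30, contractile and adhesion genes had a more negative effect: Tagln (-1.74), Csrp1 (-0.86), Vcl (-0.83), Tpm1 (-0.81), Cnn2 (-0.77) and Cnn1 (-0.64). Il11 (-2.13), Fbln1 (-0.94), Casp12 (-0.93), Krt7 (-0.92), Col1a1 (-0.91), Spry1 (-0.90), Pdgfrb (-0.88), Sparc (-0.80), Col4a1 (-0.80), Hbegf (-0.68), Ccn2 (-0.65), Sox18 (-0.56) and Jag1 (-0.52) had a more negative effect as well. Casp12 had signals of only 3.31 and 3.48 in siSox4 cells and 3.38 and 3.36 in siSox4 cells with TGFβ. Those of Pdgfrb were 4.30 and 4.41, and 4.34 and 4.34 with TGFβ. Such signals were not shown to be above background, so the sizes of these differences are uncertain. More positive effects were those of Fas (1.13), Perp (1.0), Lamb3 (0.77), Itga6 (0.75), Ddit4 (0.72), Herpud1 (0.71), Chac1 (0.68), Tgfbr1 (0.61), Ero1a (0.58), Ptch1 (0.58) and Lss (0.55). A difference can also repeat a change with siSox4 before treatment. With TGFβ, Sparc had signals of 10.15 and 10.15 in siControl and 10.13 and 10.14 in siSox4 cells. Herpud1 had 9.26 and 9.35 against 9.32 and 9.40, and Jag1 11.19 and 11.27 against 11.71 and 11.67. A more negative effect thus need not mean a lower level with TGFβ. The calls lost numbered 11 and 9 without siControl replicates 1 and 2, 29 and 30 without those of siSox4, 6 and 15 without those of siControl with TGFβ, and 26 and 29 without those of siSox4 with TGFβ. With the preset correlation, camera passed 7 lists: actin cytoskeleton and focal adhesion (adjusted p = 7.58e-06), sterol and fatty acid synthesis (0.000425), oxidative phosphorylation (0.0124), mesenchymal and EMT (0.0198), unfolded protein and amino acid stress (0.0208), and fibroblast and endothelial markers (0.033 each). With an estimated correlation none of the 7 passed. That estimate was below the preset 0.01 for oxidative phosphorylation (-0.012) and mesenchymal and EMT genes (-0.0061). A higher correlation between genes therefore does not account for the loss of these calls. For the actin list the estimate was 0.049. The alternative also tests on only 4 residual degrees of freedom, so the losses of the other lists cannot be credited to correlation alone.

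A first pattern is the more negative TGFβ effect of the actin cytoskeleton and focal adhesion list in siSox4 cells, with a median difference of -0.31 over all 30 genes. A weaker TGFβ exposure of the siSox4 cultures as a whole would lower the response of all genes, but the median ratio of the responses was 0.996 (0.933 to 1.03 without single arrays), with 1.13 for raised genes and 0.878 for lowered ones, against 0.705 for the actin list, whose genes TGFβ mostly raised. The ratio over all these genes was 0.977 after quantile normalization and 1.04 after median centring, while those of raised and lowered genes were not computed there. The list's median was -0.27 after quantile normalization and -0.21 after median centring (camera, adjusted p = 1.91e-06 and 8.93e-06). Without replicate 2 of both siControl groups it was -0.26 (adjusted p = 0.000185). A dependence of these genes on Sox4 and an off-target effect of the siRNA both stay open and were not tested.

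A further pattern is the lower signal of S phase and mitosis genes in siSox4 cells. An interferon response to the siRNA would raise interferon genes, but their upper quartile was 0.16 with TGFβ and 0.05 without, and 5 and 1 of 30 rose. A scaling that depends on brightness would move random lists of equally bright genes alike, but at most 0.04% of 10000 such lists had a median as low. Slower division after loss of Sox4, off-target effects and differences in cell density stay open and were not tested.

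The last pattern is that replicate 2 of siControl and replicate 2 of siControl with TGFβ deviated from replicate 1 in the same genes (r = 0.386 over 19937 genes). A signal range that differs between arrays would leave no correlation once a smooth trend on mean expression is removed, but r was then 0.299. Before that trend was removed, r was 0.405 in the brighter and 0.229 in the dimmer genes. Handling that these samples shared stays open, and the design names no biological difference between them.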

How the results depend on the processing

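Leaving out replicate 2 of both siControl groups and the crossed block were tests chosen after the result was seen, and the other alternatives were fixed before the data were examined. Of the named genes that were called, only Eed turned direction: for siSox4 with TGFβ its dimmer probe set gave -0.05, against 0.64 for the one used. Leaving out single arrays kept 3473 of the calls or non-calls of named genes, lost 284 and added 11. Named genes called without every array in turn were 60 of 76, 86 of 100, 90 of 93, 90 of 101 and 15 of 45 in the 5 comparisons in the order of the report. Called genes without single arrays ranged from 919 to 2537 (siSox4 without TGFβ), 2048 to 4182 (siSox4 with TGFβ), 3128 to 3541 (TGFβ in siControl cells), 2594 to 4628 (TGFβ in siSox4 cells) and 109 to 558 (difference of the TGFβ effects). Shared calls ranged from 690 to 1302 for siSox4 and 1868 to 2283 for TGFβ, opposite calls from 779 to 1249 and the ratio of TGFβ responses from 0.933 to 1.03. Such a fit has fewer arrays, and a lone array is taken to vary like the other groups.

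The difference of the TGFβ effects was called for 1082 genes without the dimmest 50% of genes, 1185 with the eBayes trend, 81 when every probe set was tested and 239 without replicate 2 of both siControl groups. Testing every probe set gave 1623 genes for siSox4 without TGFβ and 941 shared siSox4 calls. Without replicate 2 of both siControl groups the ratio of TGFβ responses was 0.949, and it was 0.938 without siControl with TGFβ replicate 1. Fry called a difference in both of these fits and not with all arrays. For these counts and ratios the cause was not tested. The median difference of the endothelial markers, -0.18, was 0.41 without the dimmest 50% of genes, where Flt1 alone is left of them. Of the list calls 31 were lost and 0 gained with an estimated correlation, 3 lost and 21 gained with fry, 7 lost and 2 gained without the dimmest 50% of genes, 18 lost and 21 gained over all fits without 1 array, and 0 lost and 3 gained with median centring.

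Deviations of replicates with the same number correlated at 0.386 between siControl and siControl with TGFβ and between -0.105 and 0.072 for other groups, so numbers were not taken as pairs. A replicate block gave 2503, 4074, 3993, 4476 and 539 genes, and a crossed block 3997 for siSox4 with TGFβ. Replicates differed across genes with an SD of 0.20 in both siControl groups and 0.15 in both siSox4 groups. The reported fit pools these spreads. Fits of only the 4 arrays compared called 2834 genes for TGFβ in siControl cells and 5583 in siSox4 cells, against 3946 and 4323 as reported. The sizes of these counts thus depend on the pooling. Signal over background was not measured here, so that dim genes without a call remain undecided. For the same reason the size of a change is uncertain for any gene that is dim on either side of a comparison.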

Other observations

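The lists in this part were added after the largest changes were seen, without the genes already seen, while the tests on them were written before their values were computed; the genes named as opposite were chosen after their values were seen.

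Genes of the enterocyte brush border, the microvillus surface of absorptive cells, rose in part in siSox4 cells. With TGFβ, of 39 such genes 12 rose and 2 fell, among them Hnf4a (1.92) and Cdx2 (1.18), transcription factors of the gut epithelium, and the microvillus genes Anks4b (1.70) and Cdhr2 (1.52). Camera gave adjusted p = 0.0078 (over 10 tests) and fry 0.0034, but with an estimated correlation the list was not called (adjusted p = 0.13), and its median was only 0.04. Without TGFβ 5 rose and none fell (median 0.09, adjusted p = 0.0126; 0.13 with an estimated correlation). TGFβ lowered 12 and raised 1 of these genes in siControl cells (adjusted p = 0.000133; 0.0951 with an estimated correlation), with Anks4b at -2.23 and Cdx2 at -1.77. In siSox4 cells it lowered 10 and raised 3 (adjusted p = 0.0126; 0.13 with an estimated correlation). For the difference of the TGFβ effects 8 genes were called higher and none lower, such as Anks4b (1.66), Hnf4a (1.60) and Lgals2 (1.39), but the list did not pass (adjusted p = 0.0997, median -0.07).

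Genes of xenobiotic metabolism, which oxidize and conjugate foreign compounds, were lower with TGFβ in siControl and in siSox4 cells. Of 45 such genes 24 fell and 3 rose in siControl cells (median -0.41, adjusted p = 1.17e-09), with Sult1c2 at -2.74, Abcc2 at -2.21 and Adh7 at -2.15. In siSox4 cells 20 fell and 5 rose (median -0.30, adjusted p = 1.03e-05), with Sult1c2 at -2.21 and Aldh1a7 at -2.05. Neither was called with an estimated correlation (adjusted p = 0.0619 and 0.0887). The difference of the TGFβ effects was positive, a weaker fall in siSox4 cells, with 4 genes called higher and none lower (median 0.07, adjusted p = 0.0126; 0.13 with an estimated correlation). With siSox4, 12 rose and 2 fell in TGFβ-treated cells (adjusted p = 0.0126; 0.13 with an estimated correlation), and 7 rose and 5 fell without TGFβ (adjusted p = 0.326).

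Among 45 genes called in opposite directions by siSox4 without and with TGFβ were the immediate early genes Fos (-0.59 and 0.73) and Egr2 (-0.81 and 0.77), and the focal adhesion gene Vcl (0.44 and -0.39).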
